A study of Mus musculus with 6 samples.

How the data were processed

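Total RNA of whole tracheas of mouse embryos at stage E18.5 was extracted from pools of 3 tracheas with Trizol, treated with DNase, purified on columns, and turned into biotin-labelled cRNA for Illumina bead arrays, per the labels' protocols. The labels give 3 wild-type pools (control) and 3 pools of embryos that lacked Sox9 in the mesenchyme (mutant), with 9 tracheas per group from 7 pregnant females. Pools were made at random, so the pool numbers 1 to 3 do not pair the groups.

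The deposited table without normalization holds, per the file headers, the mean bead intensity of each of 25697 probes on each of the 6 arrays, its standard error, the number of beads and a detection p-value. The deposited detection p-values run in steps of 1 in 798, from which the negative control signal was inferred. Rows for control probes were not used here. Per the submitters' processing notes, the authors worked with R 3.2.3 and limma 3.26.9. The deposited series values are on the log2 scale. They lie within 0.0206 of the log2 values that limma's neqc gives here from the raw table. Column medians of the series values were 5.81 or 5.82, and those of the authors' limma values were 8.23. That table lists 15335 probes, each with a detection p below 0.05 on at least 2 arrays, with the authors' log2 fold changes and p-values. Their log2 fold change equals the mean of the mutant columns minus the mean of the wild-type columns within 8e-09, the direction used here, although the file that holds it is named for the opposite difference. Of the authors' listed probes, 550 had an adjusted p below 0.05, 203 higher and 347 lower in the mutant columns, and 546 of these also passed a probe-level fit made here.

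Raw intensities were corrected and normalized with neqc in limma 3.58.1 under R 4.3.3 (normexp with background estimated from the detection p-values, an offset of 16, quantile normalization). Probes with a detection p below 0.05 on at least 3 of 6 arrays were kept, 14711 in all. Gene symbols in the file were updated through a RefSeq gene table of assembly GRCm38.p6: of 18120 symbols on the array, 12036 were current, 5218 were updated through a synonym and 866 were kept as in the file. For each symbol the kept probe with the highest mean over the 6 arrays stood for the gene, which left 10831 genes. Of the 99 named genes, 21 had more than 1 kept probe, and the probes of Fgf1 alone differed in sign.

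Differences, mutant minus control, were tested with limma's lmFit and eBayes on log2 values over all 6 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over all genes at 0.05. Adjusted p-values of single genes are from this limma fit. A gene whose probe was not above background (detection p below 0.05) on any array of a group has only a bound there, and is given as "at least N-fold": the mean of the brighter group against the dim group's mean of the higher of the probe's own value and the lowest detected value on each array. Whether a list of genes moved against the other genes was tested with limma's camera with a preset correlation of 0.01, adjusted over 37 lists of cell type markers, pathways and functions with at least 3 tested members each. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. Counts of members are given over all genes and adjusted over the list alone. A list score is the mean log2 deviation of a list's tested genes from their means over the 6 arrays.

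The groups, tests, lists and alternatives were fixed before the data were examined, except where the closing section says otherwise. The genes named were fixed by rule: Sox9, the 12 largest rises and 12 largest falls among genes that passed with all values of one group on one side of the other, leaving out predicted genes, and per list up to 4 passing members with the largest change, or up to 2 with the smallest p where none passed. Genes named as added by the adjustment over the list alone were named after their values were seen. Results of a few single genes are not reported here. Alternatives were other background corrections, offsets, normalizations, sources of the values, filters, probe summaries, variance models and thresholds, pool number as a block, and leaving out each pool in turn.

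The gene test and the list test were tried on simulated data made from the normalized gene values, with 10831 genes, 200 of them changed. Background correction, normalization, the probe filter and the choice of probe were not tested. Each simulated gene varied independently, so the rate of false list calls below holds only for lists of uncorrelated genes. In the real data the estimated correlation was 0.74 for the ciliated list and 0.10 for the chondrocyte list. With a log2 change of 0.58, 37.2% of the changed genes were recovered, with 1 it was 73.8% and with 2 it was 95.5%, and 5.08% of the calls were false. Of 40 simulated lists of 15 genes shifted by 0.5 on the log2 scale, 40 were found with the preset correlation and 31 with the estimated one, and 4 of 760 unshifted lists were called. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.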

Results

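RNA abundance was measured in whole tracheas of mouse embryos on stage E18.5 with an Illumina mouse bead array, on which each probe is read from many beads. Per the labels, 3 pools came from wild-type embryos and 3 pools from embryos that lacked Sox9 in the mesenchyme and therefore had no cartilage rings. Sox9 encodes a transcription factor required for the formation of chondrocytes. Each pool held 3 tracheas, so that each group held 9, and the embryos came from 7 pregnant females of the C57BL/6 background and were combined at random. The series names epithelial differentiation, metabolism and inflammatory genes as the subjects of the comparison. The median raw intensity was 183 to 198 on the arrays of the control pools and 205 to 211 on those of the mutant pools. Between 14468 and 14726 of 25697 probes were detected per array, with a median of 38 or 39 beads per probe. All 6 arrays lay on 1 slide with the control pools in the first positions, so array position and group cannot be told apart. The number of pools limits the precision, and the p-values measure the spread between pools, each of which averages 3 embryos.

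Sox9 itself was read at the background level of the array by 1 probe. Its raw signal was 147 ± 4.90 in the control pools and 194 ± 8.42 in the mutant pools (SD, n = 3 each). The probe was not above background on any control array (detection p 0.358 to 0.748) and was just above it on the 3 mutant arrays (detection p 0.0163 to 0.0426). On the log2 scale the means were 4.58 ± 0.09 and 5.44 ± 0.18, a change of 0.86 (SE 0.12, limma adjusted p = 0.0163). The signal of the probe was at least 1.12-fold higher in the mutant pools. In the authors' deposited table the change was 0.86 with an adjusted p of 0.0207. This direction goes against the label. The probe did not read Sox9 above background even in the control pools, where the gene was intact per the label and Col2a1 stood at 11.70. It therefore cannot serve as a check of the label, and its change is not taken as a change of Sox9. The place of the probe relative to the deleted part of the gene is not known here. The cartilage genes Col2a1, Cytl1 and Matn1 were lower in the mutant pools (log2 change -6.36, -5.56 and -2.84), the direction that a lack of cartilage rings implies. The groups are called the pools labelled control and the pools labelled mutant. The call was lost without control pool 2 (adjusted p = 0.0589) or control pool 3 (adjusted p = 0.0615), and without background correction the change was 0.27.

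Of the 12 largest falls in the pools labelled mutant 7 were in genes of the chondrocyte and cartilage matrix list, and of the 12 largest rises 3 were in genes of the interferon response list. The 12 largest falls were those of Col2a1, Cytl1, Pcolce2, Ptprv, Scin, Matn4, Hapln1, Matn1, Scrg1, Thsd4, Col9a2 and Bmper. Pcolce2, an enhancer of procollagen processing, fell (log2 change -3.53, SE 0.29, adjusted p = 0.00639), but the probe was above background on 1 of 3 mutant arrays. Its change was -2.04 by its other probe, which was detected on all 6 arrays, and -1.67 without background correction. The fit without control pool 3 gave -2.30, where the other probe stood for the gene. The first probe read 8.05 and 8.84 in control pools 1 and 2, against 4.90 to 5.42 in the mutant pools. Ptprv, a receptor tyrosine phosphatase read close to background in the mutant pools, fell by 3.30 on the log2 scale (-1.58 without background correction). Smaller falls were those of the actin-severing protein gene Scin (-3.12, and -1.76 without background correction) and the fibrillin-associated Thsd4 (-2.55, and -1.53 without background correction). The BMP-binding Bmper fell 5.51-fold. The 12 largest rises were those of Pvalb, Cox8b, Oasl2, Sftpb, Oas2, Irf7, Ear2, Fabp3, Bpifa1, Oas1g, Smim41 and Fpr2. Ear2, a secreted ribonuclease of eosinophils and macrophages, rose (log2 change 2.05, SE 0.26, adjusted p = 0.0152), by 0.75 without background correction. Fpr2, a formyl peptide receptor of phagocytes, rose by 1.74 on the log2 scale (0.63 without background correction), and Smim41, which encodes a small membrane protein, rose 3.48-fold. Oas1g belongs to a family of near-identical genes, and its rise of 1.84 (SE 0.21) may include signal of its relatives.

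Of 10831 genes tested, 598 changed, 234 of them higher and 364 lower in the pools labelled mutant (limma, adjusted p below 0.05). At least 2-fold changes were found in 151 genes, 44 higher and 107 lower. In 3406 genes (31.4%) the 3 values of one group all lay on one side of the other group, where chance gives 10%, and all 598 changed genes were among them. The first principal component held 52.7% of the variance and separated the groups. Scaled by the array median alone, 639 genes changed and 54.8% of them were higher, against 39.1% with quantile normalization. The count depended on single pools: 564 genes changed without control pool 1, 130 without control pool 2, 128 without control pool 3, 375 without mutant pool 1, 84 without mutant pool 2 and 159 without mutant pool 3. Of the 83 named genes that passed the test, 23 kept their call in each fit run without 1 pool, among them the 12 largest falls and Oasl2, Oas2, Irf7, Mx2, Ear2, Oas1g, Smim41, Ccn2, Sox18, Ccl6 and Slc26a4. The other 60 lost it in at least 1 such fit, with adjusted p up to 0.156 and no change of sign. Sizes of genes with a low signal depended on the correction: without it, 45 of 99 named changes shrank by over 1.5 times, and named genes given as at least N-fold changed by 0.18 to 1.16 on the log2 scale.

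**Figure D1:**
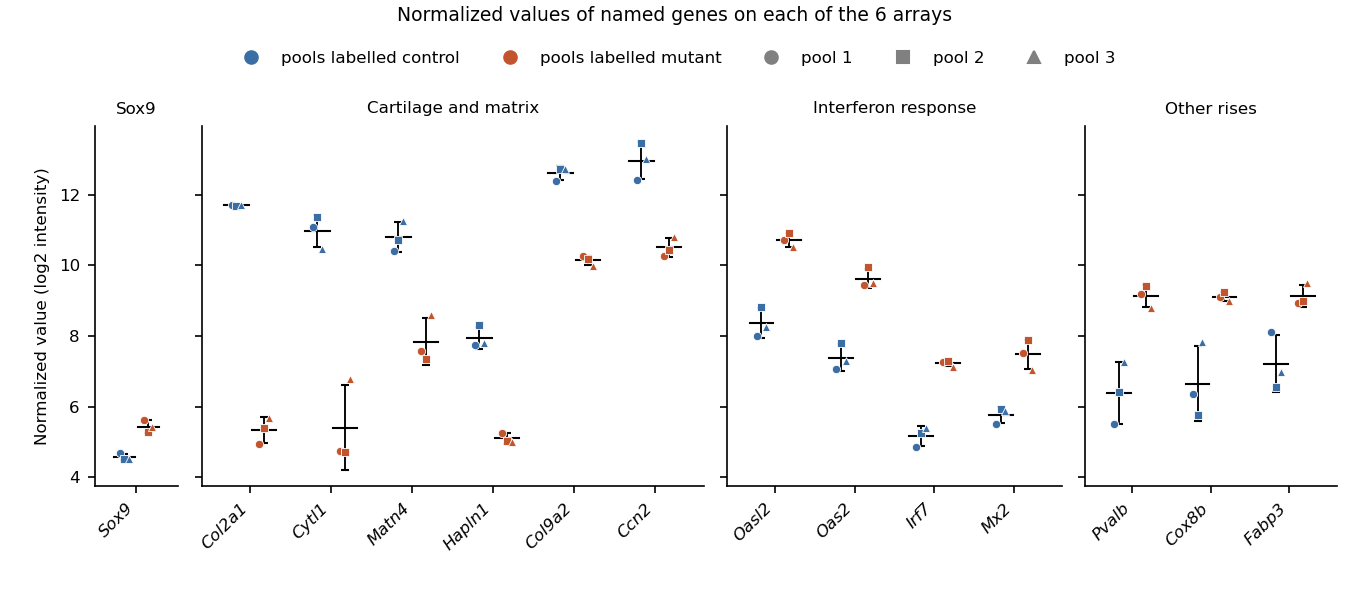
Normalized log2 intensity (y axis) of 14 named genes (x axis) on the 6 arrays, with 3 pools labelled control in blue and 3 pools labelled mutant in orange; marker shapes give the pool number, horizontal bars the group mean and error bars the SD. The control values of Col2a1 lie near 11.70 and its mutant values near 5.34, whereas those of Irf7 lie near 5.17 and 7.23.

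Cartilage genes fell steeply in the pools labelled mutant. Col2a1, the main collagen of cartilage, fell from 11.70 ± 0.02 to 5.34 ± 0.37 (log2, SD, n = 3; change -6.36, SE 0.18, adjusted p = 5.5e-05), to near background, and the change was -4.25 without background correction. Cytl1, a secreted protein of chondrocytes, fell (log2 change -5.56, SE 0.57, adjusted p = 0.00802) and was above background on 1 of the 3 mutant arrays; the change was -3.53 without background correction. The matrix protein gene Matn4 fell 7.71-fold (log2 change -2.95, SE 0.35, and -1.22 by its other probe), and Hapln1, which links hyaluronan to proteoglycan, was at least 6.47-fold lower, since its probe was not above background on any mutant array. Matn1 fell by 2.84 and Scrg1 by 2.80 on the log2 scale, both to near background (1.09 and 1.21 without background correction), and Col9a2 fell by 2.47. Of the 21 measured members of the chondrocyte and cartilage matrix list, 13 fell and 8 did not pass the test over all genes. Adjusted over the list alone, 14 fell and 1, Chad, rose. The median change of the list was -1.84, or -1.68 with undetected members at their bound, and the list test gave adjusted p = 1.1e-12, but adjusted p = 0.264 with an estimated correlation. The median was -0.50 over members detected on all 6 arrays, -0.70 without a filter on dim probes, -0.83 without background correction and -1.23 without control pool 1. The filter on all 6 arrays removes members that fell to background, among them Col2a1, Cytl1, Hapln1, Matn1 and Scrg1. The value of -0.50 therefore leaves out the steepest falls. Without control pool 1 the members also differed, since Hapln1 then failed the filter. The list score was lower in that pool (0.67) than in control pools 2 and 3 (1.04 and 1.01).

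In the list for hypertrophic cartilage and bone, Sp7, an osteoblast transcription factor, fell by 1.06 (SE 0.20, adjusted p = 0.0344) and the parathyroid hormone receptor gene Pth1r fell by 0.79 (SE 0.12, adjusted p = 0.0219) on the log2 scale. Their changes were -0.31 and -0.43 without background correction, and that of Sp7 was -0.65 with a larger offset. These were 2 of 5 measured members, and adjusted over the list alone 2 fell and 1, Ihh, rose. The list as a whole missed the threshold (median -0.43, adjusted p = 0.0872), but it was called under 6 other settings and without mutant pool 1 (median -0.68, adjusted p = 0.00625), mutant pool 2 (adjusted p = 0.00643) or mutant pool 3 (adjusted p = 0.00282). Both calls were lost without some of the pools, with adjusted p up to 0.105.

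Among 20 fibroblast genes, 5 fell and 15 did not pass over all genes: the mesenchymal transcription factor genes Twist1 (log2 change -1.28, SE 0.23) and Twist2 (-0.71, SE 0.14), the surface marker Thy1 (-1.25, SE 0.15), and the collagen genes Col5a1 (-0.62, SE 0.13) and Col1a1 (-0.55, SE 0.11), the last named after its value was seen, and adjusted over the list alone 10 fibroblast genes fell. The median was -0.57 and the list test gave adjusted p = 6.3e-07, but adjusted p = 0.264 with an estimated correlation. In smooth muscle, Actg2 (-0.86, SE 0.16) and Tagln (-0.65, SE 0.13, and -0.41 without background correction) fell, 2 of 11 members over all genes and 4 adjusted over the list alone. All 11 changes were below 0 (median -0.47, adjusted p = 0.00144, and adjusted p = 0.470 with an estimated correlation), and the median was -0.26 without mutant pool 3 and -0.31 without control pool 3. Of 14 endothelial genes, the transcription factor gene Sox18 (-0.998, SE 0.0894, adjusted p = 0.00651) and Eng (-0.68, SE 0.13) fell and Vwf rose (0.63, SE 0.11). The same 2 fell and 1 rose adjusted over the list alone. The endothelial median was -0.33 (adjusted p = 0.00369, and adjusted p = 0.418 with an estimated correlation). Of the genes named by rule in this paragraph, Sox18 alone kept its call in each fit without 1 pool, and the others reached adjusted p up to 0.139.

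Ccn2, a matricellular protein induced by TGF-beta, fell 5.49-fold (log2 change -2.46, SE 0.27, adjusted p = 0.00856). The BMP targets Id1 (-0.78, SE 0.12) and Id3 (-0.77, SE 0.09, named after its value was seen) and the activin antagonist Fst (-0.96, SE 0.17, and -0.63 without background correction) fell, and the BMP antagonist Grem1 was at least 1.31-fold lower. These were the 5 of 20 BMP and TGF-beta genes that passed, and adjusted over the list alone 10 fell. The median was -0.58, or -0.52 with undetected members at their bound (adjusted p = 1.1e-05, and adjusted p = 0.264 with an estimated correlation). It was -0.29 without background correction.

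In the Wnt list 5 of 16 genes fell: the secreted antagonists Sfrp2 (-1.34, SE 0.19), Wif1 (-0.97, SE 0.15) and Dkk3 (-0.60, SE 0.10, named after its value was seen), the ligand Wnt5a (-0.98, SE 0.20) and the Wnt enhancer Rspo3 (-0.89, SE 0.11), and adjusted over the list alone the same 5 fell and 1, Notum, rose. The median was -0.41 (adjusted p = 0.00232, and adjusted p = 0.323 with an estimated correlation). It was -0.24 without mutant pool 3, -0.20 without background correction and -0.16 without the filter on dim probes. All 18 cell proliferation genes had changes below 0 and 6 fell, among them Rrm2 (-0.70, SE 0.11), which makes DNA precursors, and the mitotic genes Kif11 (-0.64, SE 0.12, and -0.41 without background correction), Birc5 (-0.56, SE 0.12) and Plk1 (-0.52, SE 0.09). Adjusted over the list alone, 11 fell. The median was -0.41 (adjusted p = 4.7e-08, and adjusted p = 0.264 with an estimated correlation). Of the BMP, Wnt and proliferation genes named by rule, Ccn2 kept its call in each fit without 1 pool, and the others reached adjusted p up to 0.130.

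Interferon response genes rose in the pools labelled mutant. The antiviral genes Oasl2 (5.11-fold, log2 change 2.35, SE 0.22, adjusted p = 0.00751), Oas2 (4.72-fold, 2.24, SE 0.22, adjusted p = 0.00780) and Mx2 (1.71, SE 0.22, adjusted p = 0.0154) and the transcription factor gene Irf7 (2.06, SE 0.15, adjusted p = 0.00481) led the list. Irf7 was above background on 1 of 3 control arrays, and the changes of Irf7 and Mx2 were 0.73 and 0.71 without background correction. Of 20 measured members 11 rose and 9 did not pass, and adjusted over the list alone 15 rose. The median change was 0.87 and 19 of 20 changes were above 0. Its list test gave adjusted p = 1.3e-10, but adjusted p = 0.264 with an estimated correlation, and the median was 0.55 without background correction. The 4 named genes kept their calls in each fit without 1 pool.

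Inflammatory cytokines and mediators went both ways and were not called as a list. The chemokine genes Ccl6 and Cxcl9 were at least 1.81-fold (adjusted p = 0.00856) and at least 1.30-fold higher (adjusted p = 0.0288), and the acute phase gene Saa3 was at least 2.09-fold lower. Over all genes 2 of 22 members rose and 1 fell, and adjusted over the list alone 6 rose and 4 fell, the latter with Cxcl12, Csf1 and Cxcl14. The median of -0.02 lay below 0 and the mean of 0.13 above it, where the test also placed the list (adjusted p = 0.719). Cxcl9 lost its call in each of the 3 fits run without 1 pool (adjusted p up to 0.0895), and Saa3 in some of them (up to 0.0817). Among 18 antimicrobial and mucosal defence genes, of which 11 stand in another list, Bpifa1 alone rose, and adjusted over the list alone 5 rose and 4 fell (Ltf, Tlr2, Cd177 and Slpi), and the list was not called (median 0.22, and 0.08 without mutant pool 3, adjusted p = 0.457).

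None of the macrophage, neutrophil, erythroid and lymphocyte lists was called with all 6 pools and the chosen settings. The macrophage genes Aif1 (0.58, SE 0.12, 0.21 by its other probe and 0.37 without background correction) and Ms4a7 (0.55, SE 0.12) rose, 2 of 16 members, while the list was not called (median 0.04, and -0.03 to 0.15 without 1 pool, adjusted p = 0.550), and adjusted over the list alone 3 rose, with Cd14, and 1, Cd163, fell. None of 7 neutrophil genes passed limma's test over all genes (5 at unadjusted p below 0.05), and adjusted over the list alone 3 rose and 2 fell. Retnlg was at least 1.24-fold higher (adjusted p = 0.0571) and Mmp9 changed by -0.61 (SE 0.18, adjusted p = 0.0991, and -0.18 without background correction). The neutrophil list was not called (median 0.55, or 0.31 with undetected members at their bound, adjusted p = 0.572), and its median was -0.17 without mutant pool 3 and -0.52 over genes detected on all 6 arrays. Its brightest genes, Ltf and Lcn2, went from 13.94 and 10.30 to 13.51 and 9.60. Of the 7 members of the list 4 also stand in another list, so its median does not read neutrophils alone. The largest values in it, named after they were seen, were those of the calprotectin genes S100a9 (3.09, SE 0.95, adjusted p = 0.107) and S100a8 (2.67, SE 0.86, adjusted p = 0.119). In mutant pool 3 the list score was 1.40, against -0.18 and -0.10 in the other mutant pools. Slc4a1, the erythrocyte anion exchanger, fell (-0.84, SE 0.12, and -0.50 without background correction), 1 of 9 erythroid genes both over all genes and adjusted over the list alone (list median -0.09, adjusted p = 0.216). The erythroid list was called without control pool 3 (median -0.26, adjusted p = 0.0302) and with a pair of stricter detection filters (median -0.24, adjusted p = 0.0237 and 0.0265), and its median reached -0.29 without 1 pool. No lymphocyte or thymus gene passed limma's test among the 3 measured (1 at unadjusted p below 0.05), and adjusted over the list alone 1 did, Cd3g (0.74, SE 0.19, and 0.20 without background correction). The change of Ptcra was -0.24 (SE 0.21, and -0.43 to -0.06 without 1 pool). That list was not called (median -0.06, mean 0.15, adjusted p = 0.719). The calls of Aif1 and Ms4a7 were lost in each of the 6 fits without 1 pool (adjusted p up to 0.138). That of Slc4a1 was lost in some of them (adjusted p up to 0.0671).

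**Figure D2:**
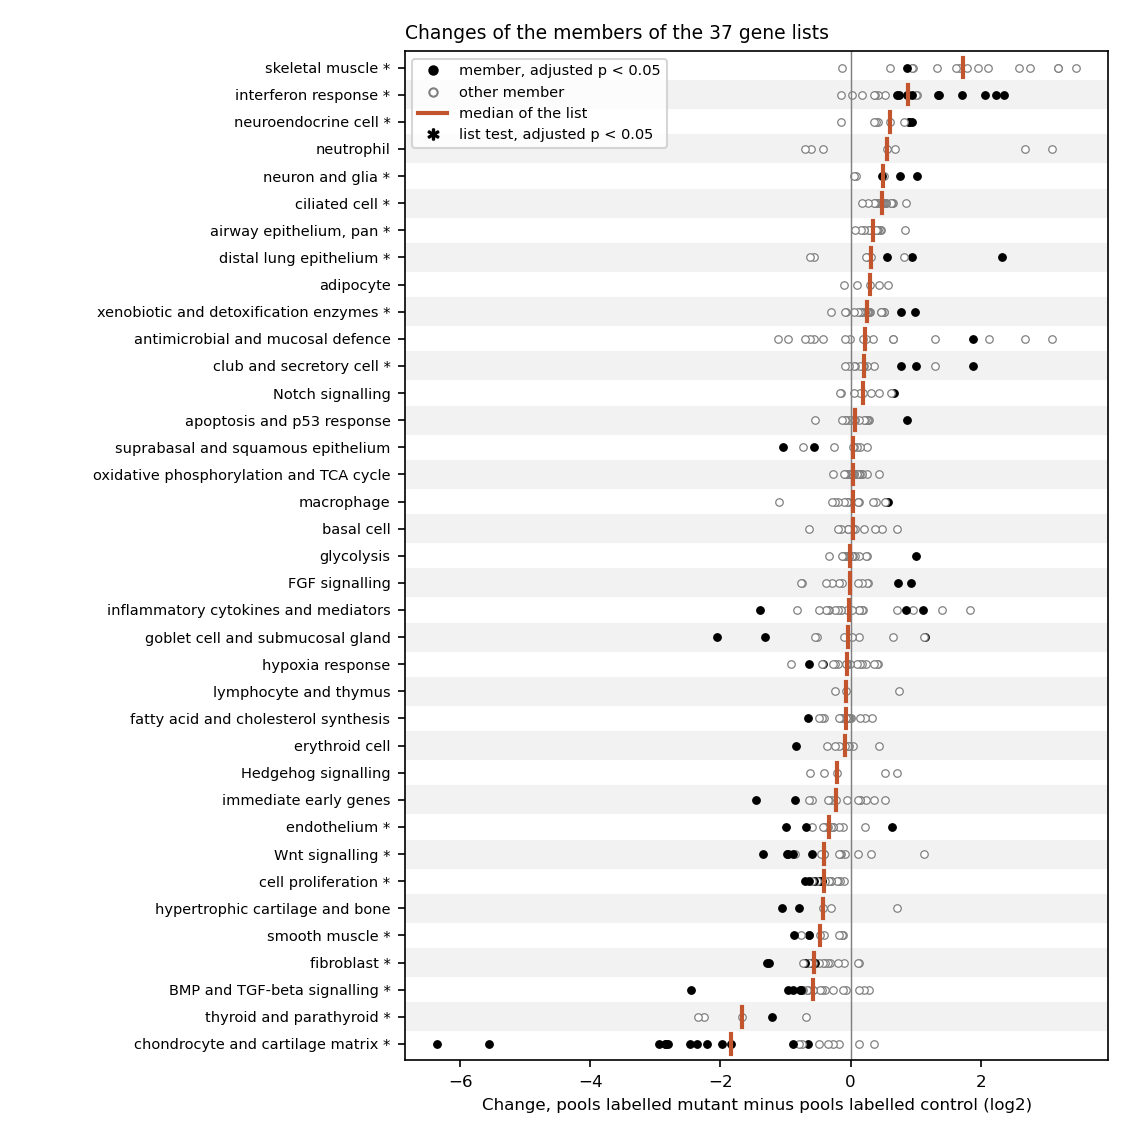
Log2 change, pools labelled mutant minus pools labelled control (x axis), of the measured members of each of the 37 gene lists (y axis, ordered by median); black points are members with adjusted p below 0.05, white points the other members, orange bars the list medians, and an asterisk marks a list with adjusted p below 0.05 in the list test with the preset correlation. The chondrocyte list has the lowest median (-1.84) and the skeletal muscle list the highest (1.73), although 1 of 16 skeletal muscle genes passed the test.

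All 16 pan-epithelial genes had changes above 0 (median 0.35), and the list test gave adjusted p = 1.1e-05, but adjusted p = 0.266 with an estimated correlation. None passed limma's test over all genes (10 at unadjusted p below 0.05) and 7 rose adjusted over the list alone, among them the transcription factor genes Foxa2 (0.84, SE 0.21, and 0.50 without background correction) and Grhl2 (0.46, SE 0.12). Of 13 club and secretory cell genes 3 rose: Bpifa1, a secreted airway defence protein (3.69-fold, log2 change 1.89, SE 0.27), the GABA receptor gene Gabrp (1.01, SE 0.16) and the aldehyde dehydrogenase gene Aldh3a1 (0.78, SE 0.16). Adjusted over the list alone, 5 rose, with Bpifb1 and Cldn10. The median was 0.21 (adjusted p = 0.00105, and adjusted p = 0.315 with an estimated correlation), and 7 of its 13 members stand in another list. All 22 ciliated cell genes had changes above 0 (median 0.48, adjusted p = 7.0e-06, and adjusted p = 0.470 with an estimated correlation). None of them passed limma's test over all genes or adjusted over the list alone (9 at unadjusted p below 0.05), with values of 0.64 (SE 0.15) for Foxj1, the master regulator of motile cilia, and 0.54 (SE 0.14) for Ccno. The ciliated median was 0.30 without control pool 1, 0.31 without mutant pool 3 and 0.29 with array weights. The 3 secretory calls were lost without some of the pools (adjusted p up to 0.139).

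Neuroendocrine genes rose in 3 of 9 cases: Ddc, which makes dopamine and serotonin (0.95, SE 0.16, and 0.61 without background correction), the synaptic vesicle gene Syp (0.90, SE 0.13) and Resp18 (0.90, SE 0.15, and 0.47 without background correction), and adjusted over the list alone 5 rose, with Scg2 and Uchl1. Nerve genes moved the same way (neuron and glia list median 0.50), and Syp is also expressed by nerves. These rises therefore do not tell neuroendocrine cells from nerves. The neuroendocrine median was 0.61 (adjusted p = 2.1e-04, and adjusted p = 0.264 with an estimated correlation). It was 0.39 without the filter on dim probes and 0.28 without background correction, and the 3 calls reached adjusted p up to 0.104 without 1 pool.

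Basal, goblet and squamous lists were not called. No basal cell gene passed limma's test over all genes (3 of 11 at unadjusted p below 0.05) and 2 rose adjusted over the list alone, Dapl1 (0.72, SE 0.20, and 0.33 without background correction) and Trp63, the master regulator of basal cells (0.47, SE 0.12); the list median was 0.03 (adjusted p = 0.668). Among 10 goblet cell and gland genes, the trefoil factor Tff1 fell 4.17-fold (-2.06, SE 0.29, adjusted p = 0.0184), the glycoprotein Gp2 fell 2.50-fold (-1.32, SE 0.22, adjusted p = 0.0259), and the mucin Muc5ac rose 2.20-fold (1.14, SE 0.23, adjusted p = 0.0442). The same 2 fell and 1 rose adjusted over the list alone (list median -0.04, adjusted p = 0.552). Of 9 squamous genes, Krtdap (-1.04, SE 0.22, and -0.62 without background correction) and Klf4 (-0.56, SE 0.12, and up to -0.06 by its other probes) fell, both also adjusted over the list alone, while the median was 0.04, the mean -0.22 and the test pointed down (adjusted p = 0.388). The goblet calls were lost without some of the pools (adjusted p up to 0.143). Both squamous calls were lost in each of the 6 fits without 1 pool (adjusted p up to 0.141). That of Klf4 was lost also under several other settings, among them median scaling and the mean of its probes.

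The neuronal Stmn2 (0.76, SE 0.14) and the autonomic transcription factor gene Phox2a (0.48, SE 0.10, and 0.25 without background correction) were among the 3 of 6 neuron and glia genes that rose, and adjusted over the list alone 4 rose, with Prph. The median was 0.50 (adjusted p = 0.00369, and adjusted p = 0.264 with an estimated correlation). It was 0.26 without background correction and 0.13 without the filter on dim probes, and the calls reached adjusted p up to 0.127 without 1 pool.

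Several large changes lay in markers of tissue that adjoins the trachea. The muscle and thyroid list scores differed strongly between pools of 1 group. Of 16 skeletal muscle genes, 15 had changes above 0 with a median of 1.73 (adjusted p = 8.9e-05, and adjusted p = 0.470 with an estimated correlation). Only Mybpc2, a fast-muscle myosin-binding protein, passed (at least 1.33-fold higher, adjusted p = 0.0407), and adjusted over the list alone it also stood alone. The list score was -1.96, -1.51 and 0.77 in the control pools and 1.53, 1.12 and 0.06 in the mutant pools. The calcium buffer Pvalb (log2 change 2.75, SE 0.42, adjusted p = 0.0211), the muscle cytochrome oxidase subunit Cox8b (2.46, SE 0.48, adjusted p = 0.0390) and the fatty acid carrier Fabp3 (1.92, SE 0.39, adjusted p = 0.0416), none of them in the tested list, rose as well, by 1.61, 1.46 and 1.25 without background correction. Fabp3 did not follow the muscle score pool by pool, with 8.11 in control pool 1 and 9.49 in mutant pool 3, where that score was lowest in each group. Pvalb and Cox8b were also higher in mutant pool 3 (8.80 and 9.00) than in control pool 3 (7.25 and 7.84). The muscle score went the other way between these pools (0.06 against 0.77). The calls of Pvalb, Cox8b and Fabp3 were lost without some of the pools (adjusted p up to 0.132), and that of Mybpc2 in each of the 3 fits run. The list median was 1.11 without background correction and 1.10 with array weights.

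Thyroid genes had changes below 0 in 5 of 5 cases (median -1.66, or -1.21 with undetected members at their bound, adjusted p = 0.00888, and adjusted p = 0.470 with an estimated correlation). The anion transporter Slc26a4, at least 2.01-fold lower (adjusted p = 0.00928), was the 1 member that passed over all genes and adjusted over the list alone. The thyroid score was -0.81, 2.43 and 0.82 in the control pools and between -0.97 and -0.52 in the mutant pools. Slc26a4 did not follow it in control pool 1, with 6.01 there against 4.95 to 5.19 in the mutant pools. The list call was lost without control pool 2 (median -0.86, adjusted p = 0.497), without control pool 3 (adjusted p = 0.234) and over genes detected on all 6 arrays (adjusted p = 0.212), and the median was -3.65 without control pool 1, -1.06 with a larger offset, -0.69 without the filter on dim probes and -0.58 without background correction.

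Distal lung genes rose in 3 of 9 cases, over all genes and adjusted over the list alone. Sftpb, a surfactant protein, rose 5.01-fold (2.32, SE 0.40, adjusted p = 0.0284), the phosphate transporter Slc34a2 was at least 1.51-fold higher (adjusted p = 0.0378) and the surfactant lipid transporter Abca3 rose by 0.55 (SE 0.12, adjusted p = 0.0453). The median was 0.32 (adjusted p = 0.0169, and adjusted p = 0.285 with an estimated correlation). Of the 9 members 2 stand in another list, and the club cell and pan-epithelial medians moved the same way (0.21 and 0.35). Whether these rises came from lung tissue or from airway epithelium was not tested. The list call was lost without mutant pool 2 (adjusted p = 0.0633) and over genes detected on all 6 arrays (adjusted p = 0.0559), and the 3 gene calls reached adjusted p up to 0.139 without 1 pool; the median was 0.52 without control pool 1 and with the mean of probes, and 0.48 with array weights. None of 5 adipocyte genes passed limma's test over all genes or adjusted over the list alone (1 at unadjusted p below 0.05), with 0.29 (SE 0.11) for Dgat2 and 0.43 (SE 0.26, and 0.21 to 0.73 without 1 pool) for Pparg, and the list was not called (median 0.29, adjusted p = 0.364), with a median of 0.02 without mutant pool 3 and 0.10 without the filter on dim probes.

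**Figure D3:**
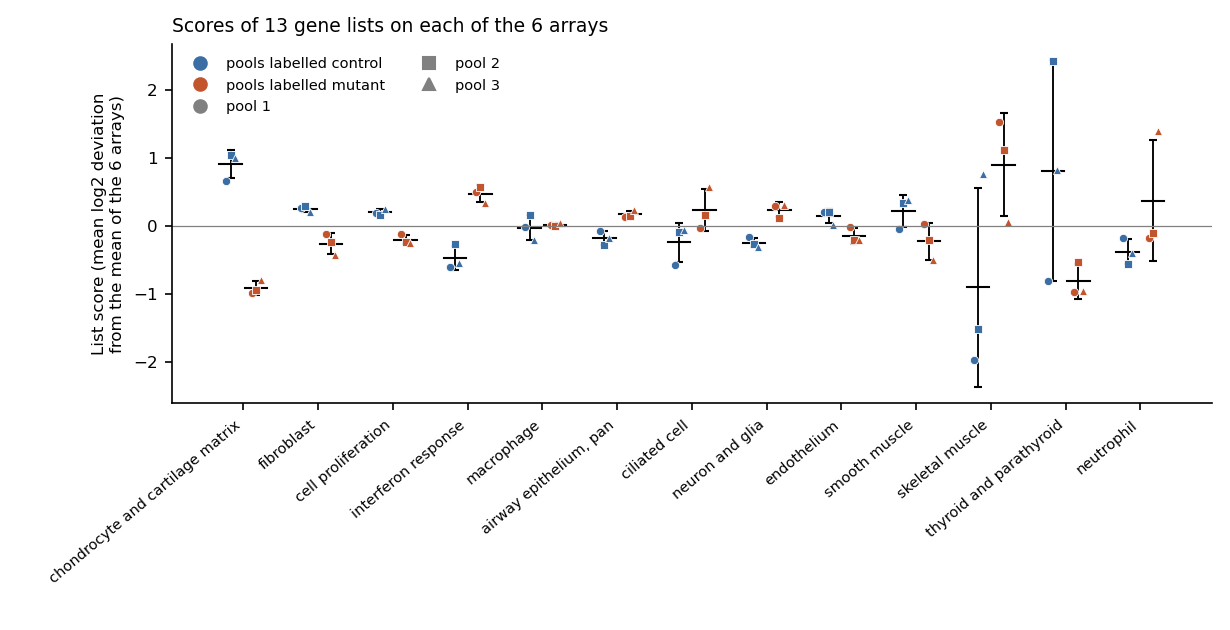
Scores of 13 gene lists (x axis) on the 6 arrays, where a score is the mean log2 deviation of the list's genes from their mean over the 6 arrays (y axis); blue marks the 3 pools labelled control, orange the 3 pools labelled mutant, shapes the pool number, horizontal bars the group mean and error bars the SD. Control pool scores of the skeletal muscle list range from -1.96 to 0.77 and those of the thyroid list from -0.81 to 2.43, whereas the interferon scores lie between -0.61 and -0.27 in the control pools and between 0.33 and 0.58 in the mutant pools.

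Of 24 xenobiotic and detoxification genes, 21 had changes above 0 and 2 rose: the glucuronosyltransferase Ugt1a6a (0.99, SE 0.14, adjusted p = 0.0174, and down to 0.41 by its other probes) and Aldh3a1, given above, and adjusted over the list alone 3 rose, with Cyp4b1. The median was 0.25 (adjusted p = 5.2e-04, and adjusted p = 0.264 with an estimated correlation), 3 of its members stand in another list, and epithelial list medians moved the same way (club cell 0.21, pan-epithelial 0.35). In glycolysis, Aldoc rose (0.997, SE 0.158, adjusted p = 0.0239), 1 of 18 genes, and adjusted over the list alone Aldoc rose and Eno1 fell. The glycolysis median was -0.0045 with a mean of 0.04, and the test pointed up (adjusted p = 0.832). No gene of 24 in oxidative phosphorylation and the TCA cycle passed limma's test over all genes or adjusted over the list alone (3 at unadjusted p below 0.05), with 0.44 (SE 0.11) for Ndufa4 and 0.25 (SE 0.08) for Uqcrc2 (list median 0.04, adjusted p = 0.388). The fatty acid elongase Elovl6 fell (-0.65, SE 0.11, adjusted p = 0.0270), 1 of 18 lipid synthesis genes over all genes and adjusted over the list alone (list median -0.07, adjusted p = 0.221), and this list was called without control pool 2 (median -0.15, adjusted p = 0.0254) and without mutant pool 3 (median -0.15, adjusted p = 0.0374). In the hypoxia list, 2 of 19 fell, P4ha1 (-0.64, SE 0.13) and P4ha2 (-0.43, SE 0.09), both prolyl hydroxylases of collagen, and adjusted over the list alone 3 fell, with Car9 (list median -0.06, adjusted p = 0.388). Each single-gene call in this paragraph was lost without some of the pools (adjusted p up to 0.156), and that of P4ha2 in each of the 6 fits. The calls of P4ha1 and P4ha2 were lost also with median scaling.

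The remaining signalling and stress lists were not called by camera with all 6 pools. Hes1, a Notch target, rose (0.67, SE 0.10, adjusted p = 0.0195), 1 of 9 Notch genes by either adjustment, including that adjusted over the list alone (median 0.18, adjusted p = 0.0952), and the list was called without mutant pool 2 (median 0.24, adjusted p = 0.0244), with a median down to 0.11 without another pool. None of 5 Hedgehog genes passed limma's test over all genes (3 at unadjusted p below 0.05), and adjusted over the list alone Ihh, at least 1.20-fold higher, and Shh rose and Smo (-0.41, SE 0.11, and up to -0.17 by its other probes) fell (median -0.20, and -0.43 to 0.01 without 1 pool, adjusted p = 0.972). Fgf1 (0.92, SE 0.17) and the FGF-induced transcription factor gene Etv4 (0.72, SE 0.15, and 0.43 without background correction) rose among 12 FGF genes, but the other kept probe of Fgf1 gave -0.11, and adjusted over the list alone the same 2 rose and Fgf9 fell, and median (-0.0094) and mean (-0.0023) lay below 0 where the test pointed up (adjusted p = 0.972). The cell cycle inhibitor gene Cdkn1a rose (0.86, SE 0.15, and 0.29 to 0.94 by its other probes), 1 of 15 apoptosis and p53 genes, and adjusted over the list alone 1 rose and 1 fell (median 0.07, adjusted p = 0.302). Of 15 immediate early genes, the matricellular Ccn1 (-1.45, SE 0.26, and -0.57 without background correction) and the flow-responsive transcription factor gene Klf2 (-0.85, SE 0.14) fell, over all genes and adjusted over the list alone (median -0.22, and -0.36 to -0.12 without 1 pool, adjusted p = 0.221). All of these calls were lost without some of the pools (adjusted p up to 0.144), and those of Fgf1 and Cdkn1a also with the mean of their probes.

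Over the 37 lists, 17 were called with the preset correlation, 9 higher and 8 lower. None was called by camera with an estimated correlation, where the lowest adjusted p was 0.264 and 5 lists had an unadjusted p below 0.05. The directional fry test called 15 lists, not all of them among the 17. It did not call the ciliated (fry adjusted p = 0.172), smooth muscle (0.139), skeletal muscle (0.172), endothelium (0.0517) and thyroid (0.0928) lists. Fry did call the lists for hypertrophic cartilage and bone (fry adjusted p = 0.0208), Notch (0.0411) and apoptosis and p53 (0.0314), which camera did not.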

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

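The setting with a detection p below 0.05 on at least 2 arrays was chosen after the data were seen, and the others before. No named gene that passed and no called list changed sign under any setting, while 1 of 580 changed genes did without mutant pool 3. Of 17 called lists, 15 kept their call under 14 other processing settings and 15 in the 6 fits without 1 pool; those that lost it were the thyroid and distal lung lists. Lists not called gained a call 8 times under other settings and 7 times without 1 pool (hypertrophic cartilage and bone, erythroid, lipid synthesis and Notch). Of 83 named genes that passed, 29 kept their call in each other setting run, and 45 of 99 named changes moved by over 1.5 times without background correction, which compresses probes of low signal. Against 598 changed genes (234 higher, 364 lower, 151 at least 2-fold), 949 changed without background correction (391 higher, 558 lower, 61 at least 2-fold), 391 without a filter on dim probes (137 higher), 1086 with a trended robust prior (456 higher, 630 lower), 1400 with array weights (626 higher, 774 lower), 62 at an adjusted p below 0.01 and 1368 below 0.1. An unmoderated gene-wise test gave 2341 genes unadjusted and 10 adjusted. Camera with an estimated correlation called 0 lists against 17, while 5 had an unadjusted p below 0.05. Fry called 15, some of them other lists than the 17. Without 1 pool, 84 to 564 genes changed (21 to 230 higher, 63 to 334 lower, 65 to 185 at least 2-fold), and the Sox9 change was 0.84 to 0.93, with its call lost without control pool 2 (0.84, adjusted p = 0.0589) and control pool 3 (0.84, adjusted p = 0.0615). Sox9 was not tested without a mutant pool, nor with the filters at 0.01 or on all 6 arrays, since its probe then failed the filter. The pool number as a block gave 123 changed genes (43 higher, 80 lower, 83 at least 2-fold). Pools that share a number did not deviate together (correlations across genes of -0.01, -0.09 and -0.10), so the numbers do not pair the pools, and the block changed no list call. Fewer pools leave fewer degrees of freedom, but each fit without 1 pool loses the same number. This does not account for the range from 84 to 564 genes. Control pool 1, without which 564 genes changed, lay apart on the second principal component (23.2, against -14.0 to 2.41 on the other arrays). For the other settings the cause was not tested. Genes near background, Sox9 among them, have sizes that depend on the correction and the offset.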

Other observations

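The 7 lists in the first 2 paragraphs and all tests of explanations below were chosen after the results were seen. Exceptions are the count of splits and the test of genes near Sox9. Since the 7 lists were chosen with these values known, their list p-values only describe them and are no independent evidence. Enzymes and chaperones that modify and crosslink procollagen were lower in the pools labelled mutant in 25 of 25 cases, and 17 of them fell over all genes (23 adjusted over the list alone). The collagen chaperone Fkbp10 fell by 0.86 (SE 0.09, adjusted p = 0.00856) and the reticulocalbin Rcn3 by 0.91 (SE 0.13, adjusted p = 0.0181) on the log2 scale, and the list median was -0.55 (adjusted p = 5.9e-16 over the 7 lists, and adjusted p = 0.0765 with an estimated correlation). Genes of tendon and ligament fell in 8 of 11 cases, 9 adjusted over the list alone (median -1.35, adjusted p = 9.1e-10, and adjusted p = 0.0988 with an estimated correlation). The small leucine-rich proteoglycan genes Omd (-2.32, SE 0.34), Prelp (-2.26, SE 0.24) and Fmod (-1.81, SE 0.21) and the fibril-associated collagen gene Col12a1 (-1.62, SE 0.16) led them. Scx did not pass (-0.74, limma adjusted p = 0.0513), and Ogn also stands in the fibroblast list. RNA of whole tracheas does not show in which cells these genes fell. Markers of lymphatic endothelium and of Lyve1-positive macrophages had changes below 0 in 9 of 9 cases and 4 fell, 9 adjusted over the list alone: Lyve1 (-1.57, SE 0.27), Fcna (-1.52, SE 0.29), Stab1 (-0.70, SE 0.09) and Ccl21a (-1.28, SE 0.15), whose near-identical copies may share its probe; the list median was -0.92 (adjusted p = 1.8e-07, and adjusted p = 0.0988 with an estimated correlation), and 2 of its members, Cd163 and Mrc1, also stand in the macrophage list weighed below with a value of 0.043.

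Nerve terminal genes rose in 11 of 19 cases and 1 fell (13 and 2 adjusted over the list alone), with Syp shared with the neuroendocrine list. The acetylcholine transporter gene Slc18a3 was at least 1.66-fold higher (adjusted p = 0.00832), and Ap3b2 rose by 1.15 (SE 0.19) and Kif5a by 1.01 (SE 0.21); the median was 0.60 (adjusted p = 8.6e-06, and adjusted p = 0.0537 with an estimated correlation). In the kallikrein list 4 of 11 genes fell and 1 rose (6 and 1 adjusted over the list alone), with Klk6 at -2.01 (SE 0.27), Klk5 at -1.99 (SE 0.24) and Klk8 at 0.58 (SE 0.11); its Klk1b members are near-identical copies, and the list median was -0.49 (adjusted p = 0.00262, and adjusted p = 0.220 with an estimated correlation). Mast cell genes had changes above 0 in 7 of 7 cases, with 1, Mcpt4, past the threshold (1.74, SE 0.33, adjusted p = 0.0347) and 5 adjusted over the list alone (median 1.48, adjusted p = 5.3e-04, and adjusted p = 0.0988 with an estimated correlation). No Y chromosome gene of 4 passed limma's test over all genes or adjusted over the list alone. The scores of these genes were -2.07, 0.28 and 0.55 in the control pools and 0.23 to 0.69 in the mutant pools (list adjusted p = 0.224). The low score was that of control pool 1, which points to a smaller share of males there. Eif2s3y had an SD of 2.74 in the control pools and 0.36 in the mutant pools. The sexes in the pools are not given in the sources used here.

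The real split of the 6 pools gave 598 changed genes, and the highest count in the other splits was 0; 1 of 10 splits gave as many as the real one. With 10 splits a share below 0.05 cannot be reached.

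The rise of interferon response genes was set against 3 technical or cellular explanations. A larger share of macrophages would have raised the macrophage list, whose score differed by 0.043 (SE 0.11) against 0.95 for the interferon list, and by 0.15 (SE 0.09) without the members shared with the Lyve1 list, while its brightest genes Cd14 and Lyz2 went from 11.03 and 11.11 to 11.56 and 11.46. The lowest median of the interferon list under other corrections and normalizations was 0.55, against 0.87. Of its 11 genes that passed 0 lie among the 100 genes nearest to Sox9, but a variant in a flanking segment of the deleted allele could act on genes elsewhere, so this count excludes nothing and such a segment stays open. A response of the tissue that lacks cartilage stays open as a hypothesis, beside array position, an infection or another difference between the litters in each pool, none of which was tested.

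The rise of the epithelial and ciliated lists may reflect the loss of cartilage cells, which raises the share of all other cells alike. The ciliated list rose by 0.77 (SE 0.31) more than the endothelial list, and the pan-epithelial list by 0.64 (SE 0.12) more. The pan-epithelial list also rose by 0.49 (SE 0.08) more than the erythroid list, so an equal gain of all other cells was not what these lists showed. These contrasts were chosen with the list values known, so they describe the lists and are no independent evidence. The pan-epithelial rise was 0.30 (SE 0.15) larger than that of the macrophage list. That gap depends on Cd163 and Mrc1, without which the macrophage score differed by 0.15 (SE 0.09) instead of 0.043, and it decides nothing. The pan-epithelial list rose by 0.27 (SE 0.08) more than the basal cell list. Members of the basal list went both ways, with 6 changes above 0 and 5 below 0. Trp63 (0.47) and Dapl1 (0.72) exceeded the pan-epithelial median of 0.35, while the bright Pdpn went from 13.06 to 12.92. The contrast therefore does not decide whether all epithelial cells gained alike. A larger share of all or some epithelial cells with a smaller share of mesenchyme and endothelium stays open. So does a change of expression within epithelial cells, since RNA of whole tracheas does not separate these.

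The muscle rise may come from unequal amounts of skeletal muscle left on the tracheas. Of the 16 list genes 10 were above background on all 3 control arrays and none stands in another list, and the brightest, Myl1 and Tnni2, went from 11.44 and 10.39 to 13.55 and 11.36. Within groups the list genes moved together between pools (median correlation across pools 0.86, highest of random lists matched on level 0.40), as unequal attached muscle predicts. If all adjoining tissue had been left on more fully, the thyroid list would have risen as well, but its score differed by -1.63 (SE 0.95), which does not decide between chance and a fall. A change of muscle with the genotype cannot be told apart from dissection in these pools.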
